A study of Mus musculus with 2 samples.

How the data were processed

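Poly(A) RNA-seq was made from bone marrow of male B6NCrl mice at 8 weeks of age, in 2 libraries of 1 group. Per the labels, the RNA was of more than 200 bases and spike-in RNAs were added. The deposited tables give estimated values per gene and per transcript for each library separately. Per the deposited notes that came with the tables, reads were placed on mm10 with the GENCODE M4 annotation and the values were made from an alignment to the transcriptome. The aligner and the quantification program are not given in the sources used here.

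The deposited expected counts are estimates of reads per gene or transcript that need not be whole, since a read that fits several genes is divided among them. The deposited TPM and FPKM correct these for effective length, which was the length minus 29 bases for 99.9% of genes, and TPM has the same total in each table. The deposited posterior mean TPM and its interval bounds lie above 0 even for genes without reads. The deposited isoform share is the percent of the gene's TPM held by a transcript. Division of reads affects near-identical copies most, and short genes gain TPM from a small effective length.

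The tables hold 43346 annotated genes, 26248 rows named by a number alone, 96 rows of ERCC spike-ins and 1 row of the phage phiX. Only annotated genes were analysed. They held 99.4% of the expected counts in each library (5360132 in replicate 1 and 5099300 in replicate 2), and the other rows stayed out of library sizes and lists. Symbols, gene types and coordinates came from GENCODE M21 on the same assembly by Ensembl gene identifier without version; 42462 genes (98.0%) matched, and the unmatched ones held 7.76% and 8.04% of the counts.

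From the deposited values, detection was counted at a TPM of at least 1 per library. Agreement was described by Pearson and Spearman correlations across genes of log2(TPM + 1). A chi-square per gene on rounded expected counts served to check whether the libraries could be 1 library deposited under 2 names. The common dispersion came from edgeR 4.0.16 (R 4.3.3, limma 3.58.1) on expected counts rounded to whole numbers, with TMM factors of 0.964 and 1.04 and genes of a mean count of at least 20. DESeq2 1.42.0 served for alternatives. No contrast between groups existed, so no difference between groups was tested and no p-value was computed.

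Ratios of replicate 1 over replicate 2 were taken on TMM-scaled CPM, which are counts divided by the effective library size, with a pseudocount of 0.5 CPM and are given as log2 values. A total of 43 gene lists for cell types, processes and controls were fixed before the data were examined; 570 of their 576 distinct genes matched a gene of the tables. For lists, members with a mean expected count of at least 20 entered, and the median was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. Lists of fewer than 3 such members (embryonic globins, osteoclasts, cartilage, mitochondrial ribosomal RNA, X inactivation) have levels only. For single genes, 2-fold differences were counted at a mean expected count of at least 100, with exact Clopper-Pearson 95% intervals of the ratio. Intervals, and the floor of 3 counts used where a library had no reads, cover counting error only, since reads without molecular identifiers are not independent molecules. At these depths a floor of 3 counts was 0.581 CPM in replicate 1. Leading isoforms were compared in genes with at least 2 transcripts and 10 TPM or more in both libraries.

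Genes were named by a rule fixed in advance: the 25 genes of highest mean TPM outside the mitochondrial genome and ribosomal proteins, up to 4 highest members of each list and listed genes under 1 TPM, the 12 largest ratios in each direction, Y-linked genes and Xist, and, for isoforms, 8 genes whose leading transcript differed and 12 genes chosen beforehand. The largest ratios were taken among genes with a symbol and a mean expected count of at least 100.

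The ratio, 2-fold and list calculations were tested on simulated counts for 5407 genes drawn from the observed means and library sizes with 200 genes changed. Of genes changed by 1.5 on the log2 scale, 97.0% were called 2-fold in the right direction, of those changed by 3, 100%, and of unchanged genes 0.0380%. A list of 20 genes shifted by 0.5 reached percentile 100, and 1.50% of 200 unshifted lists fell outside the central 95%. The simulated variation between libraries was smaller than that fitted by edgeR, a coefficient of 0.257 at a mean count of at least 100. The rates for single genes and the shifted list may therefore look better than these libraries allow. Alternatives covered other scalings, pseudocounts, filters, units, detection levels, random list schemes and the omission of each library. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.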

Results

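Poly(A) RNA was sequenced from the bone marrow of male B6NCrl mice, a sub-strain of C57BL/6, at 8 weeks of age. The series holds 1 group of 2 libraries, which the labels number as biological replicates 1 and 2. The labels describe each as marrow of an individual mouse under a separate sample record, yet both point to 1 donor record, so whether the libraries came from separate animals is left open by the labels. The expected counts summed to 5390863 in replicate 1 and to 5130893 in replicate 2 over all rows of the tables. With 1 group there was no comparison of conditions, and no difference between conditions was tested. The values below describe which cell types and processes the marrow RNA reflected, and how far the 2 libraries stood apart. Errors are SDs over the 2 libraries (n = 2). Ratios between the libraries have 1 library on each side and no replicate check.

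Transcripts of red cells and neutrophils were among the most abundant ones of nuclear protein-coding genes. The adult globins Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, which encode the chains of hemoglobin, together held 17.1% ± 11.7 of TPM, a length-corrected share of the transcripts in a library, with 25.3% in replicate 1 and 8.81% in replicate 2. Hba-a2 (ENSMUSG00000069917, chromosome 11, 32296489 to 32297298) stood at 96598 ± 50003 TPM, and Hbb-bs (chromosome 7, 103826534 to 103828096) at 28919 ± 23048 TPM. The calcium-binding proteins S100a9 and S100a8 of neutrophils and monocytes stood at 6982 ± 3358 and 5636 ± 3797 TPM, and the antimicrobial peptide gene Camp at 1753 ± 600 TPM. Genes of the mitochondrial genome held 25.05% ± 7.91 of TPM over 37 genes, and 102 ribosomal protein genes held 3.99% ± 0.0597. Coordinates are those of the GENCODE M21 annotation on GRCm38, the assembly that mm10 denotes.

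Several of the highest values belonged to pseudogenes, noncoding or very short RNAs, or genes without a symbol. Gm42418, annotated as a long noncoding RNA gene on chromosome 17, stood at 40792 ± 4372 TPM. With Gm26917 it took 8.40% ± 0.569 of the expected counts. A gene with the identifier ENSMUSG00000045999, for which the M21 annotation gave no symbol, stood at 54428 ± 2755 TPM and took 7.58% ± 0.200 of the expected counts. A block of 7 unprocessed pseudogenes on chromosome 1, classed here as mitochondrial-like, held 9.996% ± 2.75 of TPM. The block ran from Gm28439 (24611535 to 24612410) to Gm29216 (24615706 to 24616197). Reads of the mitochondrial genome may be counted there, which was not measured, so this share need not be pseudogene expression. Of these 7 pseudogenes, Gm10925 stood at 29085 ± 11068 TPM, Gm28661 at 24627 ± 497 TPM and Gm28437 at 21899 ± 7422 TPM. The remaining highest values included Mir6236 at 28883 ± 19294 TPM, Mir6240 at 1709 ± 190 TPM, Lars2 at 4211 ± 448 TPM, the small nuclear RNA Rn7sk at 1712 ± 520 TPM, the signal recognition particle RNAs Rn7s1 and Rn7s2 at 1558 ± 333 TPM each, and the ribosomal RNA gene Gm24601 at 1508 ± 731 TPM. Gm24270, Gm23935 and Gm24245 had the same value of 1577 ± 448 TPM. The values of these rows are uncertain, since reads that fit several copies may have been divided among them, which was not measured here, and since very short genes gain TPM from their small effective length. Lars2 is annotated as a long protein-coding gene, so neither reason need apply to it, and the source of its reads was not examined. Whether reads of ribosomal RNA were placed on Gm42418, Mir6236, Mir6240 or Lars2 was not examined either. Their values need not be those of transcripts of these genes.

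At a minimum of 1 TPM, 13382 genes were detected in replicate 1 and 14388 in replicate 2, a mean of 13885 ± 711. In both libraries 12185 genes passed this level, of which 10469 were annotated as protein coding. A level of 100 TPM or more in both libraries was reached by 435 genes.

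Marker lists fixed beforehand described the cell types, here the erythroid and granulocytic lineages. All 23 matched erythroid genes were at 10 TPM or more in both libraries. They included Alas2, which starts heme synthesis in red cell precursors (563 ± 313 TPM), the carbonic anhydrase Car2 (505 ± 435 TPM), the band 3 anion exchanger Slc4a1 (504 ± 158 TPM) and the blood group protein Kel (460 ± 79.9 TPM). The embryonic globins Hbb-bh1 (0.740 ± 0.170 TPM) and Hbb-y (0.690 ± 0.156 TPM) were under 1 TPM in both libraries, and Hba-x stood at 1.69 TPM in replicate 1 and 0.95 TPM in replicate 2. Of the secondary granule genes of neutrophils, 12 of 13 were at 1 TPM or more in both libraries, led by Camp, Ngp (1130 ± 549 TPM), the siderophore-binding Lcn2 (318 ± 120 TPM) and Wfdc21 (188 ± 102 TPM). The late neutrophil list summed to 1.35% ± 0.759 of TPM, and 15 of its 17 members were at 1 TPM or more in both libraries, with Retnlg at 485 ± 266 TPM and the gelatinase Mmp9 at 113 ± 37.9 TPM after S100a9 and S100a8. The primary granule genes of promyelocytes were lower, with myeloperoxidase (Mpo) at 223 ± 50.4 TPM, Prtn3 at 77.3 ± 15.0 TPM and the elastase Elane at 60.9 ± 3.90 TPM. Bpi had no reads in either library, where the limit of 3 counts corresponds to 0.581 CPM in replicate 1.

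Markers of other blood lineages were also present. All 15 megakaryocyte genes were at 1 TPM or more in both libraries, among them the integrin Itga2b (205 ± 24.98 TPM) and the platelet chemokines Ppbp (171 ± 9.84 TPM) and Pf4 (115 ± 10.9 TPM). All 20 monocyte and macrophage genes passed the same level, including heme oxygenase Hmox1 (139 ± 43.4 TPM), Ly6c2 (126 ± 59.8 TPM) and the complement gene C1qa (79.7 ± 11.8 TPM). In the B lineage, 15 of 17 early genes and 13 of 13 mature genes passed it, with the receptor chains Cd79b at 77.1 ± 18.3 TPM and Cd79a at 45.5 ± 1.84 TPM, Cd37 at 139 ± 24.8 TPM and Ighm at 137 ± 49.4 TPM. Immunoglobulin kappa (Igkc) stood at 147 ± 36.1 TPM, while 8 of 14 plasma cell genes passed the level. Of the T and NK cell genes 12 of 20 did so, none of them at 10 TPM in both libraries, and Trbc2 led with 11.5 ± 2.68 TPM. The eosinophil, basophil and mast cell list passed with 10 of 17 members, led by the granule protein Prg2 (151 ± 28.4 TPM) and the basophil protease Mcpt8 (13.2 ± 7.52 TPM). Dendritic cell genes passed with 6 of 11 members, of which Bst2 (34.1 ± 3.71 TPM) was highest. Among stem and progenitor genes 13 of 18 passed, and the transcription factors Lmo2 (67.6 ± 27.1 TPM), Tal1 (33.0 ± 8.03 TPM) and Gfi1b (28.5 ± 8.44 TPM), which erythroid precursors also express, stood highest.

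Genes of the stroma, bone and vessels of marrow were also detected. Of the niche stroma and bone genes 20 of 21 were at 1 TPM or more in both libraries, including Cxcl12, the chemokine that retains stem cells in marrow (118 ± 5.79 TPM), osteopontin Spp1 (98.8 ± 99.9 TPM), osteocalcin Bglap (93.0 ± 107 TPM) and Sparc (44.4 ± 6.68 TPM). Endothelial genes passed with 9 of 13 members, with Fabp4 (75.8 ± 17.9 TPM), which adipocytes also express, and Stab1 of sinusoids (34.0 ± 2.94 TPM) highest. Adipocyte genes passed with 4 of 10 members, including Adipoq (16.9 ± 2.35 TPM), and osteoclast genes with 3 of 9, including Acp5 (36.2 ± 1.27 TPM). Of these 3 osteoclast genes, Mmp9 also belongs to the late neutrophil list. The other 6 osteoclast genes were under 1 TPM in both libraries. All 12 skeletal muscle genes were at 1 TPM or more in both libraries, with Mylpf at 34.5 ± 28.1 TPM, Tnnt3 at 34.4 ± 1.18 TPM and the skeletal actin Acta1 at 23.9 ± 1.55 TPM. No cartilage gene reached that level in both libraries, and Sox9 stood at 0.345 ± 0.021 TPM. Of 14 genes of other organs 5 reached it, led by albumin (Alb) at 51.1 ± 32.6 TPM.

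**Figure D1:**
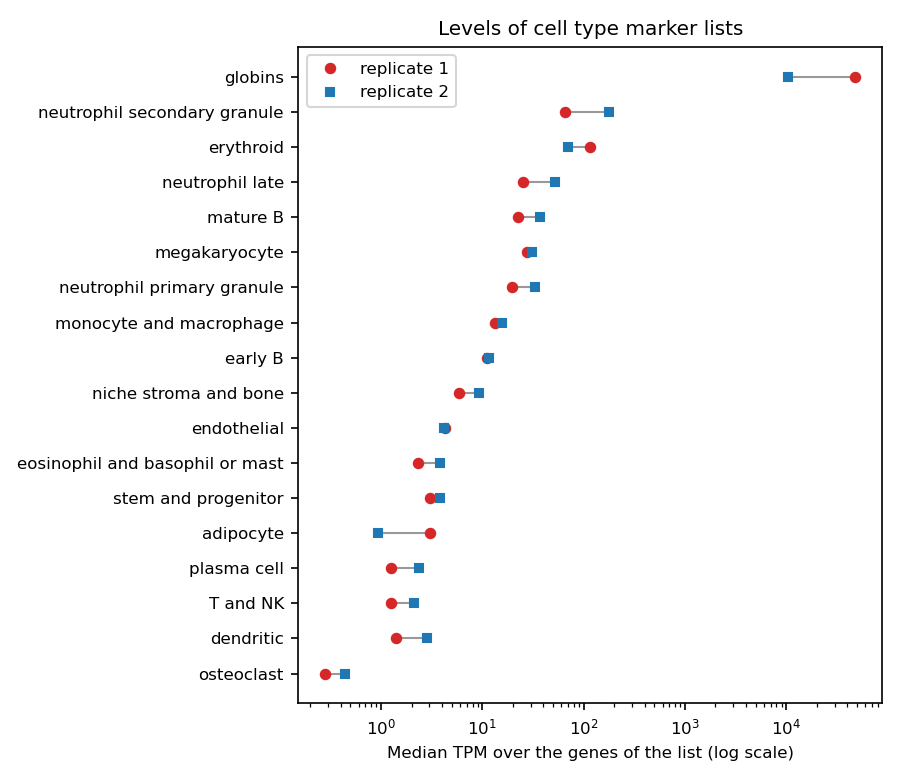
Levels of the 18 cell type marker lists. Each row is a list, the horizontal log axis is the median TPM over its genes, circles are replicate 1 and squares replicate 2, and the line joins them; the globin medians were 48143 TPM in replicate 1 and 10297 TPM in replicate 2, and the erythroid medians were 115 and 69.4 TPM.

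The levels of process lists ranged widely. The 22 large ribosomal subunit genes had a median of 358 TPM and were led by Rplp1 (2104 ± 509 TPM), and the 19 small subunit genes had a median of 471 TPM and were led by Rps9 (1710 ± 407 TPM). The 19 nuclear genes of oxidative phosphorylation had medians of 73.6 and 72.4 TPM in replicates 1 and 2, with Uqcrh at 231 ± 21.1 TPM and Atp5b at 202 ± 8.64 TPM. Both cell cycle lists were at 1 TPM or more throughout, among them the replication clamp Pcna (176 ± 105 TPM), the ribonucleotide reductase subunit Rrm2 (126 ± 66.2 TPM), Birc5 (174 ± 38.0 TPM), Ube2c (170 ± 103 TPM) and the proliferation marker Mki67 (100 ± 12.2 TPM). Iron handling genes included the ferritin chains Ftl1 (1015 ± 132 TPM) and Fth1 (662 ± 170 TPM) and the mitochondrial iron importer Slc25a37 (245 ± 73.9 TPM). Replication histones passed 1 TPM with 21 of 23 members, led by Hist1h4b (123 ± 33.1 TPM), although poly(A) selection leaves out most histone messages. Heat shock genes passed with 7 of 10 members, led by Hsp90aa1 (296 ± 176 TPM) and Hspa8 (284 ± 67.9 TPM), and unfolded protein response genes with 10 of 12, led by Calr (172 ± 9.94 TPM) and Atf4 (120 ± 39.0 TPM). Interferon response genes passed with 19 of 20 members, led by Isg15 (87.1 ± 53.3 TPM) and Rsad2 (65.8 ± 32.0 TPM). Immediate early genes passed with 11 of 16, with Klf2 at 65.2 ± 0.891 TPM, hypoxia genes with 10 of 12, with Ldha at 113 ± 11.96 TPM, and glucocorticoid response genes with 10 of 11, with Tsc22d3 at 23.0 ± 2.60 TPM. Circadian clock genes passed with 12 of 15, with Per1 at 17.3 ± 1.33 TPM. Inflammatory cytokine genes passed with only 5 of 14, of which Nfkbia (29.8 ± 5.13 TPM) was highest, and Il6 and Cxcl1 were under 1 TPM in both libraries. The housekeeping genes Actb and Ppia stood at 1329 ± 211 and 326 ± 3.29 TPM.

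The sex given in the labels was checked with 4 Y-linked genes and Xist, the RNA that silences one X chromosome in females. Eif2s3y stood at 13.4 ± 3.96 TPM, Ddx3y at 5.11 ± 0.969 TPM, Uty at 3.80 ± 0.311 TPM and Kdm5d at 2.01 ± 0.057 TPM, each above 1 TPM in both libraries. Xist stood at 0.0400 TPM in replicate 1 and 0.360 TPM in replicate 2, and its antisense partner Tsix was under 1 TPM in both. This pattern is that of male tissue, as labelled.

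Across 23549 genes with reads in either library, log2(TPM + 1) in the 2 libraries had a Pearson correlation of 0.923 and a Spearman correlation of 0.821. These are correlations across genes, which are not independent replicates. Of 5407 genes with a mean expected count of at least 100, 93.9% lay within 2-fold of each other, and the median size of the log2 ratio was 0.31. The counts differed by more than sampling noise. The median chi-square per gene with 1 degree of freedom was 5.63, against 0.455 under sampling alone, so the libraries were not 1 library deposited under 2 names and were counted as 2. The biological coefficient of variation, the square root of the common dispersion fitted by edgeR, was 0.288 over 11187 genes. It includes any difference in cell composition between the 2 marrow samples.

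**Figure D2:**
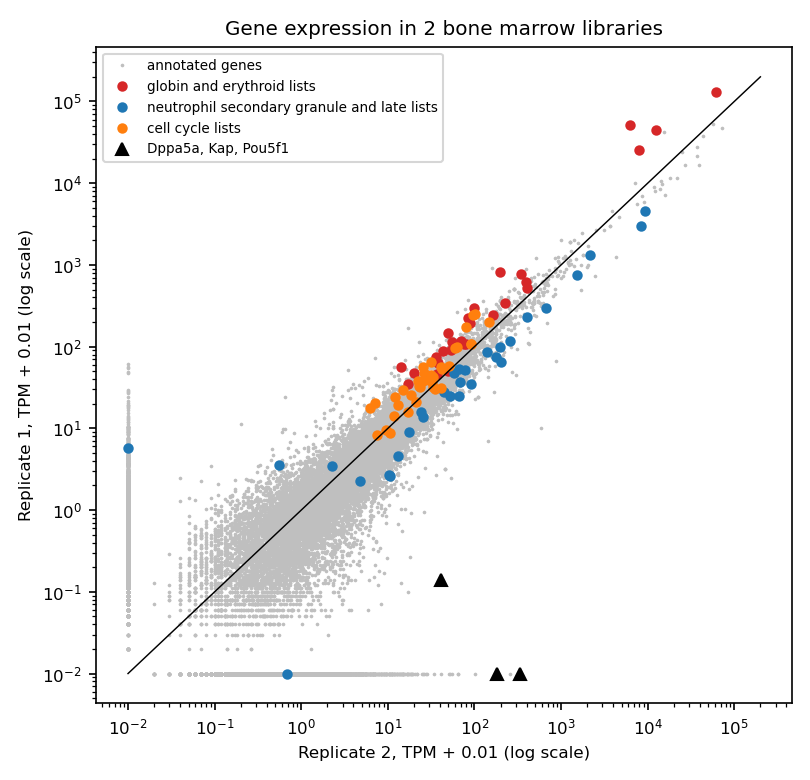
Expression of each annotated gene in the 2 libraries, in TPM plus 0.01 on log axes, with replicate 2 on the horizontal axis and replicate 1 on the vertical axis. Each dot is a gene and the line marks equal values; the globin and erythroid genes lie above the line, most neutrophil genes below it, and Dppa5a, Kap and Pou5f1 are far below it, with 0, 0 and 0.130 TPM in replicate 1.

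Red cell and neutrophil transcripts differed between the 2 libraries in opposite directions. The 23 erythroid genes were all higher in replicate 1, with a median log2 ratio of 1.11 (2.16-fold), and 13 of them were at least 2-fold higher there. The 4 globins had a median log2 ratio of 1.92, from 1.26 for Hba-a2 to 3.37 for Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465), whose sequence is shared in large part with Hba-a2. Alas2 was 3.01-fold and Car2 4.45-fold higher in replicate 1. Conversely, all 12 secondary granule genes of neutrophils were higher in replicate 2 (median log2 ratio -0.77), as were 14 of 15 late neutrophil genes (median -0.86) and 6 of 7 primary granule genes (median -0.41). S100a8 was 2.53-fold, S100a9 1.82-fold, Ngp 1.84-fold and Camp 1.47-fold higher in replicate 2. These medians lay outside the central 95% of 10000 random lists of the same size and expression, at percentiles of 100 for the globin and erythroid lists, 0 for the secondary granule and late neutrophil lists and 2.15 for the primary granule list. The percentile of the primary granule list was 4.83, inside that range, when the random lists were not matched on expression. The percentile describes these 2 libraries and is not a test between animals.

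Genes of cell division followed the erythroid genes. Of the S phase genes 17 of 18 were higher in replicate 1, with a median log2 ratio of 0.65, and of the G2 and M phase genes 18 of 19, with a median of 0.59; both lists lay above the 99th percentile of the random lists. Pcna was 2.59-fold, Rrm2 2.47-fold and Ube2c 2.78-fold higher in replicate 1. The replication histones had a median log2 ratio of 0.32 at percentile 98.6, which fell to 93.6 at a minimum mean expected count of 100 and to 96.8 with length-matched random lists. Genes of the mitochondrial genome were all higher in replicate 2, 13 of 13 with a median log2 ratio of -0.28 at percentile 0.360, while the nuclear genes of oxidative phosphorylation had a median of 0.14 at percentile 68.7. The mitochondrial list lay at percentile 6.72 among random lists not matched on expression. The genes mt-Co2 and mt-Co3 were 2.09-fold and 1.69-fold higher in replicate 2. Their values are uncertain, as reads may have been divided with the pseudogenes of chromosome 1 named above; this was not measured.

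Among the remaining cell types, mature B cell genes were higher in replicate 2 in 12 of 13 members (median log2 ratio -0.44, percentile 0.200), as were 8 of 10 eosinophil, basophil and mast cell genes (median -0.62, percentile 0.380). All 6 adipocyte genes with enough reads were higher in replicate 1 (median 0.81, percentile 99.9), with the adipokine gene Cfd at 52 reads against 3. Lists whose medians lay inside the central 95% were those of early B cells (median -0.26), monocytes and macrophages (-0.13), plasma cells (-0.33), T and NK cells (-0.41), dendritic cells (-0.07), megakaryocytes (-0.06), stem and progenitor cells (-0.09), endothelium (0.26) and niche stroma and bone (0.18). At a minimum mean expected count of 100 the stem and progenitor median was 0.73 at percentile 99.1, and the early B cell median -0.38 at percentile 1.18, both outside the central 95%. The stroma list held members that went far in opposite directions. Bglap was 10.3-fold higher in replicate 1 and its neighbour Bglap2 10.2-fold, and the collagen gene Col1a1 4.40-fold, whereas Spp1 was 4.48-fold higher in replicate 2. The expected counts of Bglap (409.04 against 38.22) and Bglap2 (193.66 against 17.06) were not whole. Reads may have been divided between these neighbours, so their ratios may not be separate. The median TPM of the stroma list was lower in replicate 1 (5.84 against 9.17 TPM), and with deposited TPM its median log2 ratio was -0.157. In the main scaling its median ratio was higher in replicate 1, as was its summed TPM.

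Of the process and control lists, the glucocorticoid response list was higher in replicate 2 in 9 of 11 members (median log2 ratio -0.54, percentile 0.760). Its call was lost with deposited TPM (percentile 8.12), and at a minimum mean expected count of 100 its median turned to 0.038. Nuclear noncoding RNAs were higher in replicate 2 in 6 of 8 members (median -0.45, percentile 0.560), with Rn7sk 1.39-fold and Malat1 1.27-fold higher. The members at least 2-fold higher there were H19 (-2.99) and Meg3 (-2.73), while 1 member was at least 2-fold higher in replicate 1. H19 is also among the largest single-gene ratios toward replicate 2 given below, so this list is not separate from them. The Y-linked list had a median of 0.64 at percentile 98.8, from 4 genes, and 93.1 with deposited TPM. Skeletal muscle genes were higher in replicate 2 in 8 of 11 members (median -0.50, percentile 1.44), with Mylpf 2.28-fold higher. Genes of other organs were so in 4 of 5 members (median -0.76, percentile 0.725), with Alb 2.37-fold higher. These 4 were all liver genes (Alb, Apoa1, Ttr and Cyp2e1). The only usable member of another organ, the brain gene Gfap, was at least 2-fold higher in replicate 1 (95 reads against 43). The median of this list therefore reflects liver genes. The muscle list lay at percentile 4.13 with deposited TPM and 6.02 after a correction for GC content and length. The medians of the lists for the cytosolic ribosome (-0.03 for the large and 0.19 for the small subunit), interferon response (0.20), iron handling (0.42), unfolded protein response (-0.27), heat shock (-0.20), immediate early genes (-0.28), inflammatory cytokines (-0.44), circadian clock (-0.38), hypoxia (-0.20) and housekeeping (0.11) lay inside the central 95%. With deposited TPM the iron handling median was 0.53 at percentile 99.8 and the unfolded protein response median -0.71 at percentile 0.0600, both outside it. After the correction for GC content and length, the unfolded protein response list (percentile 2.22) and the large ribosomal subunit list (1.60) lay outside too. Iron handling also lay outside at a minimum mean expected count of 100 (percentile 98.1) and among random lists not matched on expression (98.5), as did the circadian list among the latter (2.12). In all, 17 of 38 lists with at least 3 usable members lay outside the central 95%, 7 higher in replicate 1 and 10 higher in replicate 2. Lists of genes that vary independently would place about 1.90 there. Genes within a list may vary together and lists that share cell types are not independent, so 1.90 is no chance level for these lists.

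**Figure D3:**
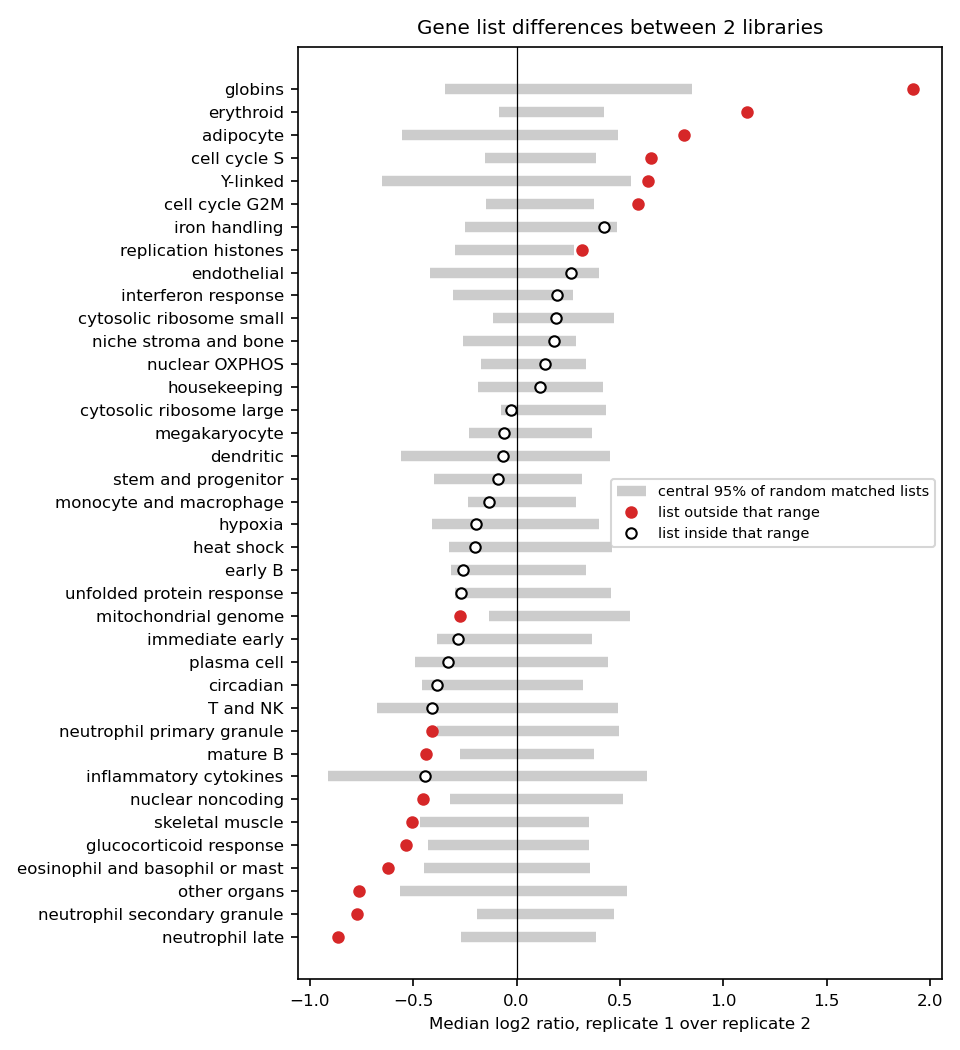
Median log2 ratio of replicate 1 over replicate 2 for the 38 gene lists. Each row is a list, filled circles lie outside and open circles inside the central 95% of 10000 random lists of like size and expression, which the grey bar spans; the values run from -0.86 for the late neutrophil list to 1.92 for the globins.

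At least 2-fold apart were 331 of the 5407 genes with a mean expected count of 100 or more, 217 higher in replicate 1 and 114 higher in replicate 2. This split depended on the scaling. It was 141 and 165 with library size alone, and 130 and 244 with deposited TPM. The median log2 ratio of all genes was -0.0068 in the main scaling, -0.11 with library size alone and -0.16 with deposited TPM. In 151 genes the exact counting interval (Clopper-Pearson, 95%) lay wholly beyond 2-fold.

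Among genes with a symbol and a mean expected count of at least 100, the 12 largest ratios toward replicate 1 included those of Hba-a1, Bglap, Bglap2, Car2, Col1a1 and Hbb-bs, given above. The others were those of the ubiquitin-conjugating enzyme gene Ube2l6 (log2 ratio 2.13), the Rh-associated glycoprotein gene Rhag (2.13), the alpha-synuclein gene Snca, which is high in red cells (2.03), the small nuclear RNA Gm23966 (2.65) and the processed pseudogenes Gm13192 (2.27) and Oaz1-ps (1.97). The counting intervals of all 12 excluded a ratio of 1, and that of Rhag ran from 1.91 to 2.39 on the log2 scale.

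The 12 largest ratios toward replicate 2 were also taken among genes with a symbol and a mean expected count of at least 100. Of these 12, Dppa5a (ENSMUSG00000060461, chromosome 9, 78367052 to 78368177) had 1096 reads in replicate 2 and none in replicate 1. This marker of pluripotent cells was at least 357-fold higher in replicate 2 with 3 counts as the floor. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762), an androgen-regulated kidney gene, had 577 reads and none, at least 188-fold higher. Pou5f1, the pluripotency factor Oct4, had 273 reads against 1, a ratio of 267 with a counting interval from 47.4 to 10566. The imprinted genes Igf2 and H19, which are high in fetal tissue, had log2 ratios of -3.63 and -2.99. The noncoding gene Gm26825 and the pseudogene Gm8430 had no reads in replicate 1 and were at least 88.0-fold and 79.9-fold higher in replicate 2. The other names were Rn7s6 (-5.48), Gm10282 (-4.14), Gm28967 (-3.50), Gm6169 (-3.40) and Gm12346 (-2.81).

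Among 3148 genes with at least 2 annotated transcripts and 10 TPM or more in both libraries, the transcript with the highest TPM was the same one in 72.5% (exact 95% interval 70.9 to 74.0). The share held by the top transcript of replicate 1 differed by a median of 9.89 percentage points between the libraries. In 3 red cell genes and the neutrophil receptor gene Csf3r that had been fixed beforehand, the same transcript led in both libraries. The leading transcript of Alas2, annotated as a processed transcript, held 57.7% ± 7.67 of the gene's TPM, that of Epb41 37.6% ± 1.36, that of Ank1 39.5% ± 1.15 and that of Csf3r 55.0% ± 12.1. The leading transcripts of the remaining genes fixed beforehand held 61.5% ± 16.7 for the leukocyte antigen Ptprc, 84.2% ± 3.43 for the glycolytic Pkm, 72.7% ± 4.48 for Bcl2l1, 79.3% ± 9.63 for Mcl1, 38.8% ± 10.4 for Tpm3, 73.1% ± 12.8 for the invariant chain Cd74 and 34.1% ± 7.33 for Runx1. For the lymphoid regulator Ikzf1 the leading transcript of replicate 1 held 51.1% there and 17.2% in replicate 2, where another led with 40.3%. The leading transcript also differed in the ferritin gene Ftl1, where one form held 76.1% in replicate 1 and 38.2% in replicate 2, and in Rplp2, Hsp90ab1, Eef1b2, Npm1, Rpl28, Fus and Rpl36al, in which no form held more than 58.1% in either library. Such shares rest on the division of short reads among overlapping transcripts.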

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

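Rows outside the annotated genes, which none of the comparisons above used, held reads above the limit of 3 counts in both libraries. Rows named by a number alone summed to 2506 expected counts in replicate 1 and 4399 in replicate 2, which was 0.0465% and 0.0857% of the counts but 0.914% and 1.78% of TPM, since these rows are short. The ERCC spike-in rows summed to 1717 and 1733 expected counts, and the phiX row to 26507 and 25461, or 0.492% and 0.496% of the counts. No control libraries were part of the series, so no background level was available for them.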

How the results depend on the processing

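The alternatives named before the data were examined are joined here by 4 chosen afterwards: the GC and length correction, summed alpha globins, and 2 restrictions to protein-coding genes. Where a value moved, the cause was not tested unless stated. Detected genes averaged 4994.5 at 10 TPM and 21126 with posterior mean TPM, which is above 0 without reads, and ranged from 13382 to 14388 when either library was left out. The correlation of 0.923 became 0.832 and 0.676 with pseudocounts of 0.1 and 0.01, 0.947 without a filter, 0.936 at a mean expected count of 20, 0.9405 at 1 TPM in both libraries, 0.9205 with FPKM, 0.954 with TMM-scaled CPM, and 0.9544 for protein-coding genes outside the mitochondrial genome. The coefficient of variation was 0.352 without a filter, 0.257 at a mean count of 100 and 0.340 with DESeq2. The number of genes at least 2-fold apart was 1049 at a mean expected count of 20 and 40 at the highest minimum tried, where more or fewer genes were counted, and 151 with the counting interval wholly beyond 2-fold. The share of genes with one leading isoform was 64.0% at 1 TPM, 87.0% at 100 TPM and 87.5% where a leading form held at least 60%. The number of lists with a median of 10 TPM or more was 22, with 22 to 24 when either library was left out and up to 29 without length correction. Between 13 and 18 lists lay outside the central 95% under the 12 alternatives. Of the 17 in the main setting, 11 lay outside under each alternative that gave a value, and all 17 kept their sign under the 4 other scalings. Of these 17, the glucocorticoid response median alone changed sign, to 0.038 at a minimum mean expected count of 100. The stem and progenitor median, inside the central 95% in the main setting, went from -0.09 to 0.73 at that same minimum. Of the 21 lists inside in the main setting, 4 changed sign under a scaling. They were stem and progenitor cells, niche stroma and bone, nuclear oxidative phosphorylation and housekeeping. No paired analysis was possible because the series holds 1 group. Depth limits the smaller values: at 5390863 and 5130893 expected counts, genes under 20 counts have wide counting intervals.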

Other observations

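The tests of precursor genes and of even dilution, the count of kidney markers used for Kap, the reading of the kidney and stem cell sums by single markers, and the use of the posterior SD of Hba-a1, were chosen after the values had been seen; the other tests were written down beforehand. Among all genes with a symbol, 109 protein-coding genes had at least 20 reads in replicate 2 and under 10% of that number in replicate 1, against 16 in the reverse direction. Of 124 markers of 10 other tissues and cell states, listed before their counts were looked at, 28 had at least 5 reads in replicate 2 and under 10% of that in replicate 1, and 0 had the reverse; none of the 28 were markers of liver, testis, intestine or pancreas and stomach. They included the pluripotency genes Tdgf1 (176 reads against 1), Esrrb (98 against 0), Nanog (74.3 against 0) and Sox2 (60 against 0), the kidney genes Acsm2 (38 against 0) and Slc34a1 (30 against 0), the airway gene Scgb1a1 (34 against 0) and the neuronal gene Stmn2 (81.2 against 4). These were picked as examples after their values were seen.

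Liver transcripts were in both libraries. The 15 liver markers not looked at before summed to 758 reads in replicate 1 and 1380 in replicate 2, 1.82-fold more (exact interval 1.67 to 1.99). The summed counts of replicate 2 over replicate 1 were 1.17 for lung, 1.13 for brain, 1.94 for heart, 0.856 for testis, 1.35 for intestine, 3.15 for skin and mesoderm of the embryo and 2.00 for pancreas and stomach, the last from 6 and 3 reads. Marrow expresses several of these markers, such as Calm2 and Nrgn, which with 932 reads held most of the brain sum in replicate 1. Outside the lists, and chosen after their values were seen, the metallothioneins Mt2 and Mt1 had log2 ratios of -2.29 and -1.23. Hspb1, a small heat shock gene picked in the same way, is a member of the heat shock list and had -4.05. The heat shock list as a whole lay inside the central 95%.

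Erythroid genes were higher in replicate 1 and neutrophil genes in replicate 2. A bias by GC content or transcript length is argued against as the whole cause, because the gap of 1.95 ± 0.176 (bootstrap SE) between the median of the erythroid genes and that of the late and secondary granule genes was 1.96 ± 0.201 after removal of smooth trends on both. Mature red cells from blood alone would leave precursor genes even, yet 13 of 13 precursor genes, such as Klf1 and Gata1, were higher in replicate 1, with a median log2 ratio of 0.757 ± 0.184. Klf1 and Gata1 also belong to the erythroid list, whose genes were already known to be higher there, so this count is no separate check. Dilution of every other cell type alike would leave neutrophil genes even with those of other cell types. Yet the median of these neutrophil genes, late and secondary granule, lay -0.705 ± 0.128 from that of 84 monocyte, megakaryocyte, B cell and stroma genes. The gap was -0.570 ± 0.124 when primary granule genes joined the first set, and the other blood lists and endothelium the second (34 against 136 genes). The list medians were known when this comparison was chosen, so the gap describes these lists and is no separate check. The lists of this wider second set were uneven, with medians from 0.26 for endothelium to -0.62 for eosinophil, basophil and mast cell genes. These SEs cover the choice of genes only, with 1 library on each side. A hypothesis that remains is that the 2 marrow samples may have held different proportions of erythroid precursors and neutrophils, from the animals or from the way marrow was taken; the design gives no group, so no biological explanation for such a difference in proportions was tested.

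Transcripts of other tissues were in replicate 2. A candidate explanation is RNA or reads of embryonic stem cells in that library: all 18 stem cell markers not looked at before had reads there, but their sum was 3.19 times that of replicate 1 (interval 2.86 to 3.57), short of the 10-fold set beforehand, since Mybl2 and Phc1, which marrow expresses, held 354 of the 416 reads of replicate 1. Misassigned reads of near-identical gene copies are argued against, as 12 of the 18 markers were nearly confined to replicate 2. For kidney, the sum of 14 markers was 1.51 times that of replicate 1 (interval 1.36 to 1.68), under the 2-fold bound set beforehand against kidney RNA; that bound was ill-chosen, since Gpx3 and Napsa held 507 of the 578 reads of replicate 1 and would hide a small share, while 5 of the 14 markers were nearly confined to replicate 2. The same sum met the prediction set beforehand for reads misassigned to Kap, that these kidney markers would differ by less than 2-fold. The count of 5 markers, added after the values were seen, goes the other way. Misassignment to Kap therefore stays open, as do RNA or reads of kidney, entered before sequencing or exchanged between libraries.

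Hba-a1 differed more between the libraries than its near-identical neighbour Hba-a2. Of the 670 windows of 30 bases in the Hba-a1 transcript, 71.5% also occur in Hba-a2, which leaves 191 windows to tell the copies apart, but this share is set by the sequence and is the same for both libraries. Hba-a1 took 29.1% of the pair's expected count in replicate 1 and 8.70% in replicate 2, whereas Hbb-bs, of which 66.9% of windows are shared with Hbb-bt, took 64.7% and 61.5% of its pair. The deposited posterior SD of the Hba-a1 count was 0.297% and 1.20% of the count, far less than the change in share, so random division of reads is too small; a steady error in the division stays open. Summed, the copies had a log2 ratio of 1.63, and a difference in the use of the genes themselves was not tested.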
